A study of Mus musculus with 16 samples.

How the data were processed

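Polyadenylated RNA of 16 liver samples of male C57BL/6J mice was measured by Illumina sequencing of mRNA libraries, from RNA of snap-frozen liver, per the labels' protocols. The groups were CCl4 (n = 3), olive oil (n = 3), PH day 0 (n = 5) and PH day 3 (n = 5), taken from the labels. Replicate numbers of the PH samples come from the labels, and those of the injection samples only name a sample. Where the labels do not say that samples came from separate animals, p-values measure only the spread between these samples.

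The authors deposited raw counts of reads per gene, 1 file per sample. Reads were counted with featureCounts 1.6.2 over the exons of each gene of Ensembl release 95 (GRCm38), reverse-stranded and without options that count multi-mapping or multi-overlapping reads, per the file headers. STAR 2.5.1, Subread and GRCm38 are named per the submitters' processing notes, without settings. Because such reads were not counted, genes with near-identical copies (Mup, Cyp2a, Cyp3a, Hsd3b) have uncertain values. The headers place injection and PH samples in 2 separate experiments, so batch and experiment cannot be told apart in the difference between the responses. Symbols and coordinates came from GENCODE M21 (Ensembl 96), which matched 54809 of 54838 gene identifiers.

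Total counts per sample were 2795909 to 8647503. Intervals and floors (3 counts in 1 sample) cover counting error only. Chi-square per degree of freedom between replicates, over genes with at least 20 counts in the pair, was 5.51 to 72.3, and no 2 files were identical, so each sample counted once.

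Counts were tested with edgeR 4.0.16 (quasi-likelihood F test, robust, TMM factors) in R 4.3.3 after filterByExpr (minimum count 10, minimum total 15), with Benjamini-Hochberg adjusted p under 0.05 as the call. CCl4 was compared with olive oil and PH day 3 with PH day 0 in separate fits, and the difference of the 2 responses in a 4-group fit of all 16 samples. The standard error is the absolute log2 fold change divided by the square root of F. CPM uses TMM factors over all samples. The shared response counts genes called the same way in both fits. For the plot of list medians, the median over members of log2(CPM + 1) was taken per sample.

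A set of 42 gene lists (897 members, 16 of them core lists for division, lipid metabolism, hepatocyte zones, detoxification, acute phase, matrix and macrophages) was tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists of at least 3 tested members, with an estimated correlation and fry as alternatives. The other lists cover sex-biased genes, stress, metabolism, clock genes and markers of other cell types. Named genes were a fixed panel of lipid, division, hepatocyte and matrix genes, the 5 risen and 5 fallen genes of largest change with mean CPM of at least 5 and no overlap between groups, the 2 members of smallest adjusted p per core list and the 1 passing member per other list. For the difference they were the 5 highest and 5 lowest contrasts and passing panel genes, and for the shared response the 5 risen and 5 fallen genes of largest smaller change. Groups, tests, lists, the naming rule and alternatives were fixed before the data were examined. Added later were the closer look at clock and male-biased genes, gene families and 1 alternative.

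Alternatives were other scalings, DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM, protein-coding genes only, an adjusted p under 0.01, an absolute log2 fold change of at least 1, the replicate number as a block, and each sample left out. On simulated counts with known changes, genes changed 1.5-fold, 2-fold and 4-fold were called in 4.54%, 37.9% and 92.2% of cases for CCl4 (11041 genes), 36.4%, 75.4% and 95.2% for PH (10400 genes) and 3.03%, 29.2% and 86.2% for the difference (11617 genes). Unchanged genes made up 10 of 97, 8 of 141 and 3 of 80 calls. Some genes that the rule names, or that are members behind a small count, are not reported here. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.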

Results

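Messenger RNA was measured by sequencing in liver of male C57BL/6J mice after 2 challenges that are followed by liver regrowth. In the injection experiment, 3 mice received carbon tetrachloride (CCl4), a solvent that hepatocytes convert to a toxic radical, mixed with an equal volume of olive oil, and 3 mice received olive oil, each at 2 µL per g of body weight into the peritoneum, with livers taken 3 days later. In the surgical experiment, partial hepatectomy (PH), the removal of part of the liver, gave 5 samples of the liver resected at day 0 and 5 samples of the liver at day 3. The series title places these samples in a study of lipid composition in the proliferating liver. Total counts per sample were 4738196 to 6218526 in the CCl4 group, 4295169 to 5221957 in the olive oil group, 3271398 to 8647503 at PH day 0 and 2795909 to 4391002 at PH day 3. A count of 3 in 1 sample corresponded to 0.369 to 1.03 CPM, TMM-scaled counts. Levels are CPM as mean ± SD and changes log2 fold changes ± SE, with n = 3 per injection group and n = 5 per PH group. Genes named without a value, mostly the members behind a count of 5 or fewer, were chosen after their values were seen. Genes said to rise or fall had an edgeR adjusted p under 0.05, other tested members of a list did not pass, and the median of a list is that of its members' log2 fold changes.

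The comparison of CCl4 with olive oil asks which transcripts changed in the liver 3 days after toxic injury. Of the genes tested, 32 of 32 of mitosis, 27 of 31 of DNA replication, 25 of 32 of the matrix and 12 of 20 of macrophages rose, and 8 of 17 of pericentral hepatocytes, around the central vein, fell. With an estimated correlation none of these lists passed with camera (adjusted p = 0.092 to 0.11). The proliferation marker Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361, minus strand of GRCm38) went from 1.94 ± 0.502 CPM to 125 ± 60.9 CPM, a change of 5.97 ± 0.51 (adjusted p = 0.00056). Glul, the glutamine synthetase of pericentral hepatocytes (ENSMUSG00000026473, chromosome 1, 153899944 to 153909723, plus strand), fell from 828 ± 47.6 CPM to 48.9 ± 10.6 CPM, or -4.10 ± 0.23 (adjusted p = 1.5e-05). Cyp2e1, the cytochrome P450 that activates CCl4 (ENSMUSG00000025479, chromosome 7, 140763739 to 140774987, plus strand), fell from 7287 ± 809 CPM to 499 ± 148 CPM, or -3.89 ± 0.30 (adjusted p = 4.5e-05). Of 11337 genes tested, 1279 rose and 1320 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 864 and 597 of them by at least 1 on the log2 scale. Library size scaling alone put 87.5% of called genes on the rising side against 49.2% here, and moved the median of all genes by 0.45 on the log2 scale.

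In the G2 phase and mitosis list after CCl4, 32 of 32 rose (32 adjusted over the list alone). The median was 5.91, camera adjusted p = 1.0e-45 (2.6e-85 to 0.16 over alternatives), adjusted p = 0.11 with an estimated correlation. Its median was 5.81 with the member that had no counts in olive oil set at its bound. Top2a, the topoisomerase of dividing cells, rose by 7.28 ± 0.39 and Aurkb by 5.46 ± 0.42. For DNA replication, 27 of 31 rose and 1 fell (29 and 1 adjusted over the list alone). The median was 2.22, camera adjusted p = 1.3e-30 (1.4e-45 to 0.18 over alternatives), adjusted p = 0.092 with an estimated correlation. Rrm1 was at 2.65 ± 0.20 and Lig1 at 3.78 ± 0.30. The fallen member was Mcm10 (-2.07), which was chosen after its value was seen. Among G1 regulators 11 of 18 rose (12 adjusted over the list alone). The median was 1.53, camera adjusted p = 9.1e-06 (2.4e-07 to 0.25 over alternatives), adjusted p = 0.092 with an estimated correlation. Rbl1 was at 4.45 ± 0.45 and cyclin D1 (Ccnd1) at 1.59 ± 0.29 (adjusted p = 0.0073). Of the p53 targets, 6 of 15 rose (6 adjusted over the list alone). The median was 0.68, camera adjusted p = 0.00064 (3.3e-05 to 0.16 over alternatives), adjusted p = 0.092 with an estimated correlation. The cell cycle inhibitor Cdkn1a was the p53 target with the smallest adjusted p, at 6.04 ± 0.65.

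The ribosome biogenesis members Nop56, Nop58, Rrp12, Nolc1 and Gar1 rose after CCl4, so that 5 of 18 rose (6 adjusted over the list alone). The median was 0.47, camera adjusted p = 0.025 (over alternatives 0.0056 to adjusted p = 0.55 with an estimated correlation), and the list's call ended without CCl4 replicate 3 (adjusted p = 0.11). Iqgap3, Diaph3 and Bub1 had no counts in olive oil and were at least 103-fold, 57.3-fold and 54-fold higher, as bounds against 3 counts over the group. Hmmr, with 1 count in olive oil and 752 in CCl4, had a ratio of 507.2 (95% counting interval 90.8 to 20060). Cdc20, an activator of mitotic exit, rose by 7.66 ± 1.32, a call that ended without CCl4 replicate 3 or olive oil replicate 1, 2 or 3 (adjusted p = 0.0502 to 0.065, 1.7e-15 to 0.25 over alternatives).

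Of the male-biased liver genes after CCl4, 15 of 22 fell (17 adjusted over the list alone). The median was -2.60, camera adjusted p = 1.0e-15 (over alternatives 2.9e-24 to adjusted p = 0.092 with an estimated correlation). Susd4 was at -2.91 ± 0.22. Several members, such as the Mup genes, have near-identical copies and their single values are uncertain. Among cytochrome P450s of drug metabolism, 12 of 21 fell (13 adjusted over the list alone). The median was -1.43, camera adjusted p = 1.2e-09 (5.6e-21 to 0.16 over alternatives), adjusted p = 0.092 with an estimated correlation. Cyp2c38, with 221 counts in olive oil and 2 in CCl4, had a ratio of 0.0061 (95% counting interval 0.00073 to 0.0223). In the pericentral hepatocyte list 8 of 17 fell (9 adjusted over the list alone). The median was -1.43, camera adjusted p = 2.6e-08 (4.8e-17 to 0.13 over alternatives), adjusted p = 0.11 with an estimated correlation. In the periportal list 1 of 22 rose and 6 fell (1 and 8 adjusted over the list alone). The median was -0.54, camera adjusted p = 0.039 (over alternatives 0.00021 to adjusted p = 0.47 with an estimated correlation). Sult5a1 changed by -1.85 ± 0.22 and the periportal cadherin Cdh1 rose by 1.46 ± 0.20. The periportal call ended without CCl4 replicate 2 (adjusted p = 0.13), and its median was -1.05 without CCl4 replicate 1. Other large falls named by rule were in the glutamate transporter Slc1a2 (-8.01 ± 0.84), Cyp2a5 (-6.28 ± 0.88) and Cyp2a21-ps (-6.34 ± 0.41), the last 2 being close paralogs.

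Mup-ps4, a pseudogene among near-identical copies, was at least 242-fold lower after CCl4, a call that ended without CCl4 replicate 1, 2 or 3 or olive oil replicate 3 (adjusted p = 0.06 to 0.085, 9.9e-10 to 0.1 over alternatives). Of hepatocyte secreted proteins and transcription factors, 6 of 28 fell (7 adjusted over the list alone). The median was -0.29, 0.08 with library size scaling, camera adjusted p = 0.038 (over alternatives 0.00021 to adjusted p = 0.65 with an estimated correlation). Hpd was at -1.64 ± 0.28. That list's call ended without CCl4 replicate 2 or 3 (adjusted p = 0.099 to 0.1), and its median was -0.45 without CCl4 replicate 1. Albumin (Alb) was 74000.0 ± 7137 against 73350.0 ± 5681 CPM, with a fitted change of the opposite sign to these means, -0.01 ± 0.27 (adjusted p = 0.99). Of the female-biased liver genes Abcd2 rose (2.28 ± 0.27) and Cyp2a4 fell, so 1 of 9 rose and 1 fell (1 and 1 adjusted over the list alone). The median was -0.84, camera adjusted p = 0.52. It was -0.60 (adjusted p = 0.035, 0.035 to 0.81 over alternatives) without CCl4 replicate 1. Among oncofetal and progenitor genes Afp, Cd24a and Ly6d rose, so 3 of 7 rose (3 adjusted over the list alone). The median was 0.99, camera adjusted p = 0.0085 (over alternatives 0.00081 to adjusted p = 0.33 with an estimated correlation). Afp was at 2.98 ± 0.38. The oncofetal median was 1.91 without CCl4 replicate 1, 2.08 without CCl4 replicate 3, and 2.77, 3.00 and 3.06 without olive oil replicates 1, 2 and 3.

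For fatty acid synthesis after CCl4, 4 of 15 fell (4 adjusted over the list alone). The median was -0.81, camera adjusted p = 0.0064 (7.6e-05 to 0.61 over alternatives), adjusted p = 0.59 with an estimated correlation. The fallen members were Mlxipl, a carbohydrate-sensing activator of lipogenesis (-1.63 ± 0.28), Slc25a1 (-0.71 ± 0.17), Thrsp and Mid1ip1, and the call of Slc25a1 ended without CCl4 replicate 2 or olive oil replicate 1 (adjusted p = 0.0546 to 0.059, 0.00037 to 0.29 over alternatives). Fatty acid synthase (Fasn) did not pass, at -1.26 ± 0.47 (adjusted p = 0.1), and passed with DESeq2, at -1.25 (adjusted p = 0.012, 0.012 to 0.31 over alternatives). For fatty acid elongation and desaturation, 2 of 17 fell (2 adjusted over the list alone). The median was -0.08, 0.37 with library size scaling, camera adjusted p = 0.61. Elovl3 fell (-3.89 ± 0.45), as did Tecr (-0.64 ± 0.16), whose call ended without olive oil replicate 1 or 3 (adjusted p = 0.058 to 0.072, 0.003 to 0.55 over alternatives). The panel members Elovl1 (-0.08), Elovl6 (-0.45), Fads1 (-0.05) and Fads2 (-0.19) did not pass, with adjusted p from 0.39 to 0.89. Elovl5 was at 0.68 ± 0.25 (adjusted p = 0.08), and passed at 0.89 (adjusted p = 0.026, 0.004 to 0.27 over alternatives) without CCl4 replicate 3.

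The desaturase Scd1 (ENSMUSG00000037071, chromosome 19, 44394451 to 44407709, minus strand) was at 0.17 ± 1.38 (adjusted p = 0.95), with 15.9 CPM in CCl4 replicate 1 against 573 and 1341 CPM in replicates 2 and 3. Without CCl4 replicate 1, Scd1 was at 0.75 (adjusted p = 0.32, 0.32 to 0.99 over alternatives), and without CCl4 replicate 3 at -0.95. Scd2 was at 1.88 ± 0.74 (adjusted p = 0.12), the lipase gene Pnpla2 at -0.49 ± 0.48 (adjusted p = 0.52) and the phosphatidylethanolamine methyltransferase Pemt at -0.28 ± 0.17 (adjusted p = 0.27). These 3 passed without CCl4 replicate 1, at 2.29 (adjusted p = 0.004, 0.004 to 0.28 over alternatives), -1.20 (adjusted p = 3.8e-05, 3.8e-05 to 0.81 over alternatives) and -0.40 (adjusted p = 0.033, 0.033 to 0.6 over alternatives). In triglyceride synthesis and lipid droplets, 5 of 25 fell (5 adjusted over the list alone), namely Fitm1 (-4.75 ± 0.42), Dgat2 (-1.38 ± 0.18), Gpat4, Lipe and Mgll, with median -0.17, 0.27 with library size scaling, camera adjusted p = 0.067. It was -0.28 (adjusted p = 0.0013, 0.0013 to 0.62 over alternatives) without CCl4 replicate 1.

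For phospholipid synthesis and acyl remodelling, 1 of 26 rose and 4 fell (1 and 4 adjusted over the list alone). The median was 0.04, camera adjusted p = 0.73 and a mean of -0.01. Choline kinase (Chka) rose by 2.86 ± 0.26. The acyltransferase Lpcat3 fell (-0.91 ± 0.13, adjusted p = 0.0009), as did Chpt1, Etnk2 and Pcyt2, and the Lpcat3 call ended with library size scaling (-0.47, adjusted p = 0.0873, 1.5e-06 to 0.087 over alternatives). In sphingolipid metabolism, Sptlc2, Cers6, Sgms1 and Cerk rose and Smpd2, Sgpp1 and Gba2 fell, so 4 of 28 rose and 3 fell (5 and 4 adjusted over the list alone). The median was 0.11, camera adjusted p = 0.83. Smpd2 was at -1.40 ± 0.18 and Gba2 at -1.67 ± 0.27. Of cholesterol synthesis genes, 2 of 25 fell (2 adjusted over the list alone), which were Tm7sf2 (-1.35 ± 0.22) and Stard4 (-0.62 ± 0.15), with median -0.13, 0.32 with library size scaling, camera adjusted p = 0.54. It was -0.34 (adjusted p = 0.023, 0.023 to 0.94 over alternatives) without olive oil replicate 3. The Stard4 call ended without CCl4 replicate 3 or olive oil replicate 1 (adjusted p = 0.0522 to 0.059, 0.0034 to 0.52 over alternatives).

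In bile acid synthesis and transport after CCl4, 1 of 24 rose and 11 fell (1 and 12 adjusted over the list alone). The median was -0.89, camera adjusted p = 1.0e-05 (5.5e-10 to 0.25 over alternatives), adjusted p = 0.16 with an estimated correlation, including the oxysterol hydroxylase Cyp7b1 at -2.67 ± 0.22 and the uptake transporter Slco1b2 at -1.74 ± 0.21, while Cyp39a1 rose. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, did not pass (-0.87 ± 1.09, adjusted p = 0.63), with 8.68 CPM in CCl4 replicate 1 against 91.8 and 219.8 CPM in the others, and was at -0.33 without it. For fatty acid oxidation and ketogenesis, 8 of 29 fell (11 adjusted over the list alone). The median was -0.44, camera adjusted p = 0.00087 (over alternatives 7.5e-07 to adjusted p = 0.59 with an estimated correlation), led by Acaa1b (-2.34 ± 0.23) and Eci1 (-1.08 ± 0.17). Of lipoproteins and lipid uptake, 2 of 30 rose and 9 fell (3 and 10 adjusted over the list alone). The median was -0.36, 0.08 with library size scaling, camera adjusted p = 0.0508. Abcg5 was at -1.49 ± 0.18, and Cd36 and Apom the risen members. That list passed without CCl4 replicate 1, at -0.34 (adjusted p = 0.0034, 0.0034 to 0.56 over alternatives), and without olive oil replicates 1 and 2, at -0.33 (adjusted p = 0.0466) and -0.48 (adjusted p = 0.049).

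For the extracellular matrix and myofibroblast list after CCl4, 25 of 32 rose and 1 fell (25 and 1 adjusted over the list alone). The median was 2.30, camera adjusted p = 1.2e-16 (5.0e-24 to 0.18 over alternatives), adjusted p = 0.11 with an estimated correlation. Collagen type I (Col1a1) rose from 8.41 ± 2.13 CPM to 122 ± 46 CPM (3.84 ± 0.35, adjusted p = 0.00039), vimentin (Vim) by 2.29 ± 0.25 and smooth muscle actin (Acta2) by 2.57 ± 0.50 (adjusted p = 0.0061), and Col5a3 fell (-2.15 ± 0.17). The Acta2 call ended with limma-voom (adjusted p = 0.0766, 1.6e-10 to 0.077 over alternatives). In the monocyte and infiltrating macrophage list, 12 of 20 rose (15 adjusted over the list alone). The median was 1.64, camera adjusted p = 1.0e-12 (1.8e-19 to 0.19 over alternatives), adjusted p = 0.092 with an estimated correlation. Gpnmb, a gene of lipid-laden macrophages, had 4 counts over the olive oil samples and 44.9 ± 5.85 CPM after CCl4 (7.04 ± 0.32), and Mmp12 had a ratio of 41.8 (95% counting interval 14.1 to 205). Among hepatic stellate cell genes Dcn, Pdgfrb, Pdgfra and Hgf rose and Ecm1 fell (-0.79 ± 0.14), so 4 of 17 rose and 1 fell (4 and 1 adjusted over the list alone). The median was 0.79, camera adjusted p = 0.086. That list passed without CCl4 replicate 1, at 1.00 (adjusted p = 0.0062, 0.0062 to 0.69 over alternatives), and without olive oil replicates 1 and 2, at 0.89 (adjusted p = 0.047) and 0.86 (adjusted p = 0.03).

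In the Kupffer cell list after CCl4, Id3 rose and Timd4, Nr1h3 and C6 (-1.37 ± 0.23) fell, so 1 of 14 rose and 3 fell (1 and 3 adjusted over the list alone). Cell source was not tested. The median was -0.58, camera adjusted p = 0.41. Of the liver endothelial cell genes Flt4, Lyve1 and Stab1 (0.99 ± 0.16) rose, so 3 of 22 rose (2 adjusted over the list alone). The median was 0.18, camera adjusted p = 0.34. Red blood cell transcripts were lower in CCl4, where Hba-a1 was 30.5 to 49.1 CPM against 80.5 to 97.8 CPM in olive oil. In that list 5 of 5 fell (5 adjusted over the list alone). The median was -1.08, camera adjusted p = 5.9e-05 (over alternatives 4.3e-07 to adjusted p = 0.32 with an estimated correlation). Alas2 was at -2.61 ± 0.31. Of the mitochondrial genome transcripts mt-Nd2, mt-Nd4, mt-Nd5, mt-Nd6 and mt-Co1 fell, so 5 of 7 fell (7 adjusted over the list alone). The median was -0.80, camera adjusted p = 0.017 (over alternatives 0.00011 to adjusted p = 0.53 with an estimated correlation), and they took 3.31 ± 0.172% of counts against 4.29 ± 0.452% in olive oil. The mt-Nd6 call (-0.69 ± 0.16) ended without olive oil replicate 3 (adjusted p = 0.061, 0.00081 to 0.52 over alternatives). Of neutrophil genes none of 3 passed with edgeR, DESeq2 or limma-voom (0 at an unadjusted p under 0.05 with edgeR, 0 adjusted over the list alone). The median was 1.44, camera adjusted p = 0.63. That median was -0.06 without CCl4 replicate 1. In the cholangiocyte list, where Spp1 rose (1.71 ± 0.35), 1 of 3 rose (2 adjusted over the list alone). The median was 1.05, camera adjusted p = 0.2. It was 1.49 (adjusted p = 0.042, 0.012 to 0.5 over alternatives) without olive oil replicate 1.

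Of adipocyte genes, 1 of 3 fell (1 adjusted over the list alone) after CCl4, with median -1.89, camera adjusted p = 0.39, the fallen member being Pparg (-1.89 ± 0.51), whose call ended without CCl4 replicate 3 or olive oil replicate 1 or 3 (adjusted p = 0.064 to 0.1, 0.0019 to 0.1 over alternatives). The B and plasma cell list had 2 tested members, of which Igkc fell (-1.78 ± 0.45), a call that ended without olive oil replicate 1 or 2 (adjusted p = 0.067 to 0.07, 0.005 to 0.07 over alternatives). No T and NK cell gene and 1 exocrine pancreas gene were tested, the latter without passing, so none of these 3 lists was tested as a set.

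CCl4 replicate 1 differed from the other CCl4 samples in Igfbp1 (1726 against 70.4 and 21 CPM) and Mt1 (1565 against 16.2 and 21.7 CPM). Among immediate-early genes, Fos, Jun, Egr1, Ier2 and Klf6 (2.49 ± 0.36) rose and Dusp1 fell, so 5 of 15 rose and 1 fell (5 and 1 adjusted over the list alone). The median was 1.25, camera adjusted p = 0.036 (0.00023 to 0.6 over alternatives), adjusted p = 0.59 with an estimated correlation. Without CCl4 replicate 1 the median of this list was 0.00 (adjusted p = 0.16, 0.00023 to 0.6 over alternatives). For gluconeogenesis and fasting, Pdk4 rose and Gcgr fell (-1.10 ± 0.18), so 1 of 14 rose and 1 fell (1 and 1 adjusted over the list alone). The median was -0.30, camera adjusted p = 0.73 and a mean of 0.41. Without CCl4 replicate 1 this list passed with a median of -1.19 (adjusted p = 0.00028, 0.00028 to 0.92 over alternatives), and the median was 0.15 and 0.17 without CCl4 replicates 2 and 3. Of the NRF2 and glutathione genes, Hmox1, Txnrd1, Srxn1, G6pdx and Gsr rose, so 5 of 16 rose (6 adjusted over the list alone). The median was 1.02, camera adjusted p = 0.07. It passed without CCl4 replicate 1, at 1.39 (adjusted p = 1.2e-07, 1.2e-07 to 0.73 over alternatives), and without olive oil replicates 1, 2 and 3, with adjusted p of 0.047, 0.0258 and 0.0472. The Gsr call (1.05 ± 0.26) ended without CCl4 replicate 2 or olive oil replicate 1, 2 or 3 (adjusted p = 0.062 to 0.089, 2.7e-08 to 0.089 over alternatives).

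Of the acute phase genes, 1 of 26 rose and 2 fell (1 and 2 adjusted over the list alone) after CCl4, with median 0.48, camera adjusted p = 0.78, the members being Saa4 (-1.88 ± 0.30), Crp and Steap4 (1.04 ± 0.23). The median was -0.50 without CCl4 replicate 1. The Steap4 call ended without olive oil replicate 1 or 3 (adjusted p = 0.059 to 0.07, 1.3e-06 to 0.07 over alternatives). Of the interferon-stimulated genes, Oas1a (2.04 ± 0.45), Gbp2, Gbp3, Bst2 and Ifi27l2a rose, so 5 of 18 rose (8 adjusted over the list alone). The median was 0.91, camera adjusted p = 0.014 (0.0016 to 0.4 over alternatives), adjusted p = 0.32 with an estimated correlation. In the unfolded protein and integrated stress response list, 7 of 20 rose and 3 fell (9 and 3 adjusted over the list alone). The median was 0.54, camera adjusted p = 0.076. Manf was at 1.33 ± 0.16, and Herpud1, Chac1 and Ero1lb fell. The list passed without CCl4 replicate 3, at 0.59 (adjusted p = 0.029, 0.025 to 0.66 over alternatives). For glycolysis, Pfkp and Pkm rose and the glucose transporter Slc2a2 fell (-1.83 ± 0.20), so 2 of 19 rose and 1 fell (2 and 1 adjusted over the list alone). The median was 0.25, camera adjusted p = 0.83. In the circadian clock list, Arntl, Clock and Npas2 rose and 11 others fell, so 3 of 18 rose and 11 fell (4 and 12 adjusted over the list alone). The median was -1.34, camera adjusted p = 1.6e-05 (3.8e-08 to 0.13 over alternatives), adjusted p = 0.092 with an estimated correlation. Tef was at -1.84 ± 0.15. Fry, which tests each list by itself, ended the calls of fatty acid synthesis, fatty acid oxidation, the hepatocyte list and immediate-early genes, the last also lost with limma-voom and library size scaling. Library size scaling ended the calls of Ecm1, Hsd3b5, Igkc, Lpcat3, Pparg, Slc25a1, Stard4, Tecr and mt-Nd6, limma-voom those of Acta2, Cdc20, Cenpe and Mup-ps4, and no low-count filter those of Hsd3b5 and Mup-ps4.

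**Figure D1:**
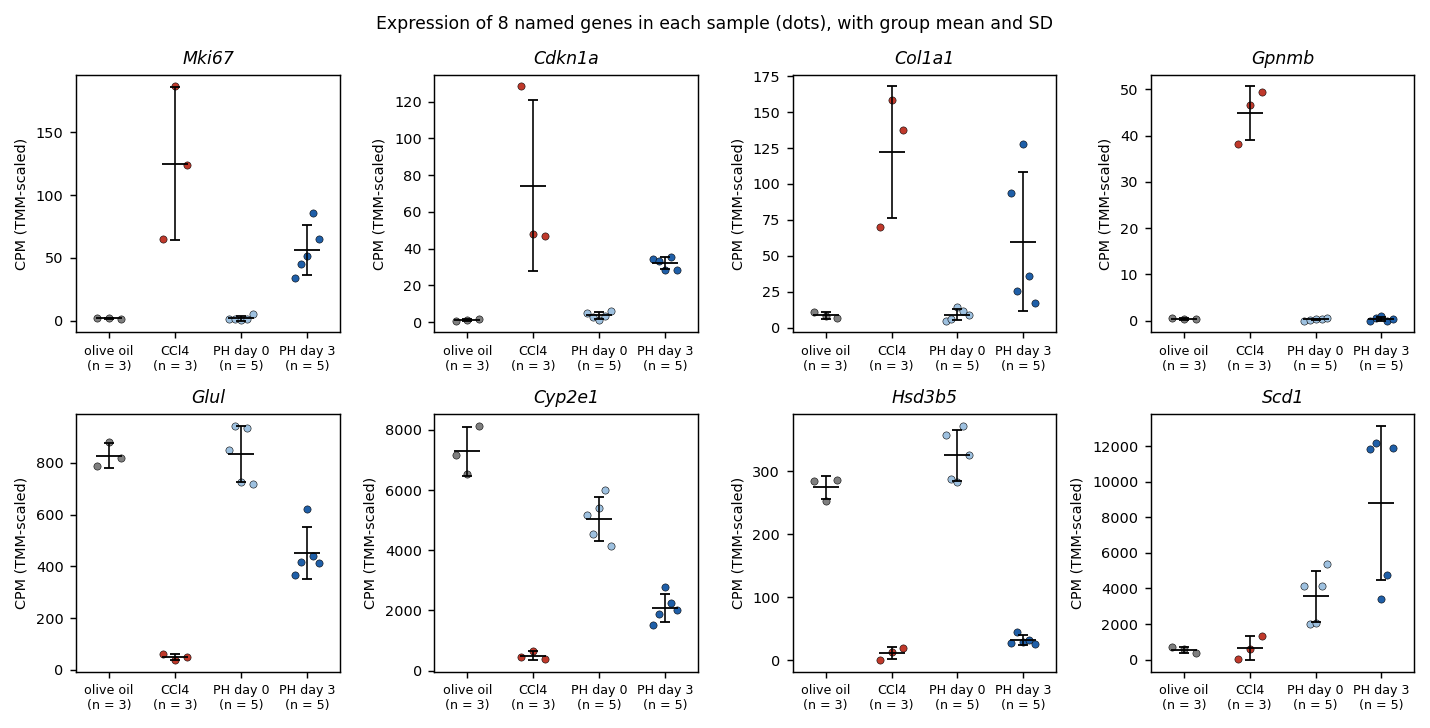
TMM-scaled CPM (linear axes) of 8 named genes in each sample, with 1 dot per sample and bars for the group mean and SD (n = 3 per injection group, n = 5 per PH group). Mki67 was 65.2 to 187 CPM after CCl4 and 33.7 to 85.9 CPM at PH day 3, above all samples of the control groups, and Scd1 spanned 15.9 to 1341 CPM among the CCl4 samples.

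The comparison of PH day 3 with PH day 0 asks which transcripts changed in the remaining liver 3 days after surgery. Of the genes tested, 31 of 31 of mitosis, 11 of 17 of NRF2 and glutathione and 15 of 27 of the matrix rose, 18 of 22 male-biased genes fell, and of 24 bile acid genes 10 fell and 3 rose. With an estimated correlation the mitosis and male-biased lists passed (adjusted p = 0.0084 and 0.0065), and the NRF2, matrix and bile acid lists did not (adjusted p = 0.12, 0.15 and 0.12). Mki67 went from 1.91 ± 1.95 CPM to 56.2 ± 20.1 CPM (4.87 ± 0.50, adjusted p = 0.00013), and Hsd3b5, a male-biased steroid dehydrogenase, fell from 326 ± 40.4 CPM to 31.8 ± 7.97 CPM (-3.34 ± 0.14). Glul fell from 835 ± 109 CPM to 452 ± 99 CPM (-0.87 ± 0.13, adjusted p = 5.1e-05) and Cyp2e1 from 5046 ± 728 CPM to 2082 ± 465 CPM (-1.26 ± 0.14, adjusted p = 2.0e-06). Of 10546 genes tested with edgeR, 1026 rose and 845 fell, 419 and 162 of them by at least 1 on the log2 scale. Library size scaling alone put 78.9% of called genes on the rising side against 54.8% here, and moved the median of all genes by 0.14. No sham operation was analysed here, and the resected and the remaining tissue can come from different lobes, so surgery and lobe are not separated from time.

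In the G2 phase and mitosis list after PH, 31 of 31 rose (31 adjusted over the list alone). The median was 4.28, camera adjusted p = 4.5e-90 (over alternatives 2.2e-140 to adjusted p = 0.0084 with an estimated correlation). Ccna2 was at 3.86 ± 0.27 and Ccnb2 at 4.70 ± 0.31. For DNA replication, 13 of 28 rose (16 and 1 adjusted over the list alone). The median was 0.80, camera adjusted p = 3.2e-10 (over alternatives 4.6e-15 to adjusted p = 0.033 with an estimated correlation), led by the ribonucleotide reductase genes Rrm2 (2.67 ± 0.24) and Rrm1. Of the p53 targets, 7 of 13 rose (9 adjusted over the list alone). The median was 0.56, camera adjusted p = 5.2e-07 (over alternatives 1.8e-11 to adjusted p = 0.0084 with an estimated correlation). Cdkn1a was at 3.15 ± 0.24. Among G1 regulators Ccnd1 (1.38 ± 0.22, adjusted p = 0.0012), Cdkn2c (1.64 ± 0.24), E2f1, E2f2 and Rbl1 rose, so 5 of 15 rose (5 adjusted over the list alone). The median was 0.38, camera adjusted p = 0.0059 (over alternatives 0.00014 to adjusted p = 0.13 with an estimated correlation). Of ribosome biogenesis genes none of 18 passed with edgeR, DESeq2 or limma-voom (0 at an unadjusted p under 0.05 with edgeR, 0 adjusted over the list alone). The median was 0.01, -0.01 with upper-quartile scaling, camera adjusted p = 0.95 and a mean of -0.01. The largest rises named by rule were Slpi (6.60 ± 0.66), Cdkn3 (6.13 ± 0.48), Hmmr (5.54 ± 0.41), Cenpe (5.32 ± 0.54) and Gsta1 (5.28 ± 0.90). Each PH day 0 sample had 0 to 2 counts of Slpi, 0 to 3 of Cdkn3 and of Cenpe, 0 to 7 of Hmmr and 1 to 7 of Gsta1. The sizes of these rises are therefore uncertain.

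Of the male-biased list after PH, 18 of 22 fell (19 adjusted over the list alone). The median was -1.38, camera adjusted p = 4.1e-33 (over alternatives 8.7e-56 to adjusted p = 0.0065 with an estimated correlation). The female-biased members Cyp3a16, Cyp3a41a, Cyp3a41b, Cyp3a44 (1.39 ± 0.15) and Abcd2 rose, so 5 of 9 rose (6 adjusted over the list alone). The median was 1.39, camera adjusted p = 3.4e-06 (over alternatives 1.6e-10 to adjusted p = 0.12 with an estimated correlation), and the Cyp3a members are near-identical copies whose single values are uncertain. The largest falls named by rule were Hsd3b4 (-3.97 ± 0.27), Gm4956 (-3.81 ± 0.43), Mup-ps4 (-3.73 ± 0.75), Ces4a (-3.34 ± 0.36) and Hsd3b5, of which Mup-ps4, Hsd3b4 and Hsd3b5 have close copies. In the pericentral list Slc22a3 and Ahr rose and others fell, so 2 of 18 rose and 6 fell (2 and 8 adjusted over the list alone). The median was -0.36, camera adjusted p = 0.014 (over alternatives 0.00012 to adjusted p = 0.64 with an estimated correlation). Cyp1a2 was at -0.67 ± 0.10. For the periportal list 5 of 22 rose and 5 fell (6 and 5 adjusted over the list alone). The median was 0.01, -0.01 with upper-quartile scaling, camera adjusted p = 0.98. Hsd17b13 was at 0.74 ± 0.10 and Sult5a1 at -1.45 ± 0.20. Sdsl, Apoa4, Uroc1 and Aldh1b1 also rose, and Otc, Hal, Cyp2f2 and Pigr fell. Of the cytochrome P450s of drug metabolism, 5 of 20 rose and 8 fell (5 and 10 adjusted over the list alone). The median was -0.30, camera adjusted p = 0.26. Cyp3a11 (1.45 ± 0.13), Cyp2c55 (2.65 ± 0.24), Cyp2c38, Por and Nr1i2 were the risen members.

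Alb (0.77 ± 0.11, adjusted p = 2.4e-05), Trf, Ambp and Ahsg rose after PH in the list of hepatocyte secreted proteins and transcription factors, where 4 of 28 rose and 7 fell (5 and 10 adjusted over the list alone). The median was -0.03, 0.10 with library size scaling, camera adjusted p = 0.47. Proc was at -0.62 ± 0.09. Among NRF2 and glutathione genes, 11 of 17 rose (12 adjusted over the list alone). The median was 0.79, camera adjusted p = 5.7e-08 (over alternatives 5.1e-11 to adjusted p = 0.12 with an estimated correlation). Gsta4 was at 1.12 ± 0.14. Of the acute phase genes, 2 of 24 rose and 2 fell (2 and 2 adjusted over the list alone). The median was 0.53, camera adjusted p = 0.11, the members being Cp, Apcs, Crp (-0.43 ± 0.13) and hepcidin (Hamp, -2.02 ± 0.35). That list passed without PH day 0 replicate 12, at 0.83 (adjusted p = 0.011, 0.0087 to 0.84 over alternatives), and without PH day 3 replicates 13 and 16, at 0.67 (adjusted p = 0.018) and 0.70 (adjusted p = 0.0092). The Crp call ended without PH day 0 replicate 12 or 13 or PH day 3 replicate 12, 13 or 16 (adjusted p = 0.058 to 0.066, 5.4e-05 to 0.072 over alternatives). Of the oncofetal and progenitor genes, Ly6d rose (4.50 ± 0.60), so 1 of 5 rose (2 adjusted over the list alone). The median was 0.42, camera adjusted p = 0.076, and the list passed without PH day 0 replicates 13 and 15 and PH day 3 replicate 12, at 0.63 (adjusted p = 0.0041), 0.45 (adjusted p = 0.044) and 0.31 (adjusted p = 0.037), with 0.0041 to 0.32 over alternatives.

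In bile acid synthesis and transport after PH, 3 of 24 rose and 10 fell (3 and 10 adjusted over the list alone). The median was -0.23, camera adjusted p = 0.0004 (over alternatives 8.7e-06 to adjusted p = 0.12 with an estimated correlation). Cyp7b1 was at -1.89 ± 0.10 and Cyp27a1 at -0.74 ± 0.10. Cyp7a1 (0.84 ± 0.22, adjusted p = 0.024), Cyp39a1 and Akr1d1 rose. The Cyp7a1 call ended without PH day 0 replicate 16, 13 or 15 or PH day 3 replicate 16 (adjusted p = 0.0527 to 0.061, 0.0001 to 0.21 over alternatives). For fatty acid elongation and desaturation, Scd2 (2.76 ± 0.52, adjusted p = 0.0062), Elovl1 (0.62 ± 0.12, adjusted p = 0.00067) and Fads3 rose and Elovl3 fell (-1.75 ± 0.24), so 3 of 16 rose and 1 fell (3 and 1 adjusted over the list alone). The median was 0.13, camera adjusted p = 0.46. Scd1 went from 3549 ± 1460.0 CPM to 8820.0 ± 4346 CPM without passing (1.33 ± 0.46, adjusted p = 0.091), but passed without PH day 3 replicate 14, at 1.53 (adjusted p = 0.044, 0.01 to 0.48 over alternatives), and with DESeq2, at 1.33 (adjusted p = 0.01). Elovl5 (0.16), Elovl6 (0.73), Fads1 (-0.07), Fads2 (-0.14) and Fasn (0.31) did not pass, with adjusted p from 0.17 to 0.75.

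For fatty acid synthesis, Acaca rose and Slc25a1 (-0.41 ± 0.09), Mlxipl (-0.41 ± 0.09) and Mid1ip1 fell after PH, so 1 of 15 rose and 3 fell (1 and 3 adjusted over the list alone). The median was -0.06, 0.07 with library size scaling, camera adjusted p = 0.91 and a mean of 0.03. In triglyceride synthesis and lipid droplets, Dgat2 fell (-0.64 ± 0.09) and Lpin2 rose (0.57 ± 0.12), so 1 of 24 rose and 1 fell (1 and 1 adjusted over the list alone). The median was 0.05, camera adjusted p = 0.96 in the downward direction. Among phospholipid synthesis and acyl remodelling genes Chka (1.06 ± 0.13) and Lpgat1 rose and Pcyt2 (-0.42 ± 0.08), Chpt1 and Ptdss1 fell, so 2 of 24 rose and 3 fell (4 and 3 adjusted over the list alone). The median was 0.08, camera adjusted p = 0.66. Lpcat3 (0.07), Pemt (-0.04) and Pnpla2 (-0.10) did not pass, with adjusted p of 0.7, 0.83 and 0.59. Of sphingolipid metabolism, Sptlc2 (0.80 ± 0.14), Cers6, Smpd3 and Asah1 rose and Sphk2 (-0.57 ± 0.12), Gba2 and Ormdl2 fell, so 4 of 27 rose and 3 fell (4 and 3 adjusted over the list alone). The median was 0.02, camera adjusted p = 0.8.

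In cholesterol synthesis, 2 of 24 rose and 7 fell (2 and 7 adjusted over the list alone) after PH, with median -0.26, camera adjusted p = 0.074. Tm7sf2 was at -0.64 ± 0.09. The list passed without PH day 0 replicate 13 or 15 or PH day 3 replicate 12, at -0.32 (adjusted p = 0.0054), -0.34 (adjusted p = 0.0025) and -0.30 (adjusted p = 0.02), with 0.0025 to 0.76 over alternatives. For fatty acid oxidation and ketogenesis, Acadm (0.49 ± 0.09) was among the risen and Eci1 among the fallen members, where 4 of 29 rose and 3 fell (4 and 4 adjusted over the list alone). The median was -0.06, 0.07 with library size scaling, camera adjusted p = 0.96, a mean of 0.13 and the test upward. Of lipoproteins and lipid uptake, 8 of 30 rose and 12 fell (8 and 12 adjusted over the list alone). The median was -0.18, camera adjusted p = 0.3. Apoa5 was at -0.93 ± 0.11.

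In the extracellular matrix and myofibroblast list, 15 of 27 rose (20 and 1 adjusted over the list alone) after PH, with median 1.23, camera adjusted p = 1.3e-12 (over alternatives 2.2e-19 to adjusted p = 0.15 with an estimated correlation). Col4a1 rose by 1.46 ± 0.12, Loxl2 by 2.69 ± 0.31 and Col1a1 by 2.76 ± 0.66 (adjusted p = 0.021), the last a call that ended without PH day 0 replicate 16, 12 or 15 (adjusted p = 0.0512 to 0.0553, 6.7e-05 to 0.078 over alternatives). Acta2 did not pass (2.17 ± 0.73, adjusted p = 0.072) but did without PH day 3 replicate 15, at 2.45 (adjusted p = 0.013, 0.00027 to 0.24 over alternatives). For the monocyte and infiltrating macrophage list Cd9 (1.33 ± 0.19) and Lgals3 (1.21 ± 0.42) rose, so 2 of 10 rose (2 adjusted over the list alone). The median was 0.42, camera adjusted p = 0.15, and the Lgals3 call ended without PH day 0 replicate 16, 13, 14 or 15 or PH day 3 replicate 12, 14 or 15 (adjusted p = 0.0533 to 0.12, 0.0073 to 0.12 over alternatives). The macrophage list passed without PH day 0 or PH day 3 replicate 13, at 0.51 (adjusted p = 0.018) and 0.57 (adjusted p = 0.017), with 0.0033 to 0.73 over alternatives. Of the stellate cell genes Rgs5, Ngfr, Pdgfrb, Pdgfra and Nes (2.39 ± 0.41) rose and Ecm1 fell, so 5 of 17 rose and 1 fell (6 and 1 adjusted over the list alone). The median was 0.47, camera adjusted p = 0.093. It passed without PH day 0 replicates 13 and 14 and PH day 3 replicate 13, at 0.74 (adjusted p = 0.029), 0.46 (adjusted p = 0.039) and 0.50 (adjusted p = 0.031), with 0.0046 to 0.7 over alternatives.

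Liver endothelial genes Kdr (-0.84 ± 0.14), Clec4g, Fcgr2b, Dnase1l3 and Mrc1 fell after PH, so 5 of 23 fell (5 adjusted over the list alone). The median was -0.09, 0.05 with library size scaling, camera adjusted p = 0.18. It was -0.16 (adjusted p = 0.0483, 0.0483 to 0.84 over alternatives) without PH day 3 replicate 16. Of the Kupffer cell genes, 1 of 13 rose and 2 fell (1 and 2 adjusted over the list alone). The median was -0.13, 0.00 with library size scaling, camera adjusted p = 0.66 and a mean of 0.08, Marco being higher and Slc40a1 and C6 (-0.74 ± 0.10) lower. For red blood cell transcripts 1 of 5 fell (1 adjusted over the list alone). The median was -0.49, camera adjusted p = 0.058, Alas2 being the fallen member, and Hba-a1 at 187 to 496 CPM at day 0 and 177 to 465 CPM at day 3. That list passed without PH day 0 replicates 13 and 14 and PH day 3 replicate 14, at -0.51 (adjusted p = 0.04), -0.66 (adjusted p = 0.0049) and -0.80 (adjusted p = 0.0018), with 9.1e-13 to 0.7 over alternatives. Of the mitochondrial transcripts, 1 of 7 fell (1 adjusted over the list alone). The median was -0.17, camera adjusted p = 0.51. The mt-Nd5 call (-0.36 ± 0.12) ended without any 1 sample but replicate 15 of either day (adjusted p = 0.0547 to 0.11, 0.00064 to 0.51 over alternatives). In the adipocyte list Fabp4 rose and Car3 fell (-1.40 ± 0.17), so 1 of 3 rose and 1 fell (1 and 1 adjusted over the list alone). The median was -0.47, camera adjusted p = 0.2.

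Of cholangiocyte genes none of 3 passed with edgeR, DESeq2 or limma-voom (0 at an unadjusted p under 0.05 with edgeR, 0 adjusted over the list alone) after PH, with median -0.09, 0.05 with library size scaling, camera adjusted p = 0.92 and a mean of 0.15. Cela1, the exocrine pancreas gene tested, fell (-1.25 ± 0.15), 2 B and plasma cell genes and 1 T and NK cell gene did not pass, and no neutrophil gene was tested. Of the unfolded protein and integrated stress response genes Hspa5 (0.67 ± 0.10), Dnajb9, Hyou1, Pdia4 and Manf rose and Trib3 and Xbp1 fell, so 5 of 19 rose and 2 fell (6 and 2 adjusted over the list alone). The median was 0.14, camera adjusted p = 0.15. It passed without PH day 0 replicate 12 or PH day 3 replicate 16, at 0.36 (adjusted p = 0.011) and 0.25 (adjusted p = 0.0457), with 0.011 to 0.7 over alternatives. Of the interferon-stimulated genes, with Irf7 (-0.84 ± 0.14) among the fallen, 4 of 16 fell (1 and 4 adjusted over the list alone). The median was -0.27, camera adjusted p = 0.26. For immediate-early genes, Btg2 (1.44 ± 0.22) and Klf6 rose and Ier2 fell, so 2 of 13 rose and 1 fell (3 and 3 adjusted over the list alone). The median was 0.25, camera adjusted p = 0.46.

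In gluconeogenesis and fasting, Igfbp1, Irs2 and Sik1 rose and Gcgr fell (-0.60 ± 0.10) after PH, so 3 of 14 rose and 1 fell (5 and 1 adjusted over the list alone). The median was 0.41, camera adjusted p = 0.12. It was 0.53 (adjusted p = 0.033, 0.0029 to 0.7 over alternatives) without PH day 3 replicate 13. Of glycolysis, Hk1, Tpi1 (0.36 ± 0.08), Pkm and Ldha rose and Gapdh fell, so 4 of 19 rose and 1 fell (4 and 1 adjusted over the list alone). The median was 0.17, camera adjusted p = 0.45. Clock (0.55 ± 0.13) and Npas2 rose and Per3 fell in the circadian clock list, so 2 of 16 rose and 1 fell (2 and 2 adjusted over the list alone). The median was 0.12, camera adjusted p = 0.96 and a mean of -0.07. With an estimated correlation, 4 of the 10 lists called after PH passed, which were G2 phase and mitosis, DNA replication, p53 targets and male-biased liver genes. Limma-voom ended the calls of Col1a1, Gsta1, Lgals3 and Mup-ps4, library size scaling 4 calls including Crp, Mlxipl and mt-Nd5, and upper-quartile scaling that of Lgals3.

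**Figure D2:**
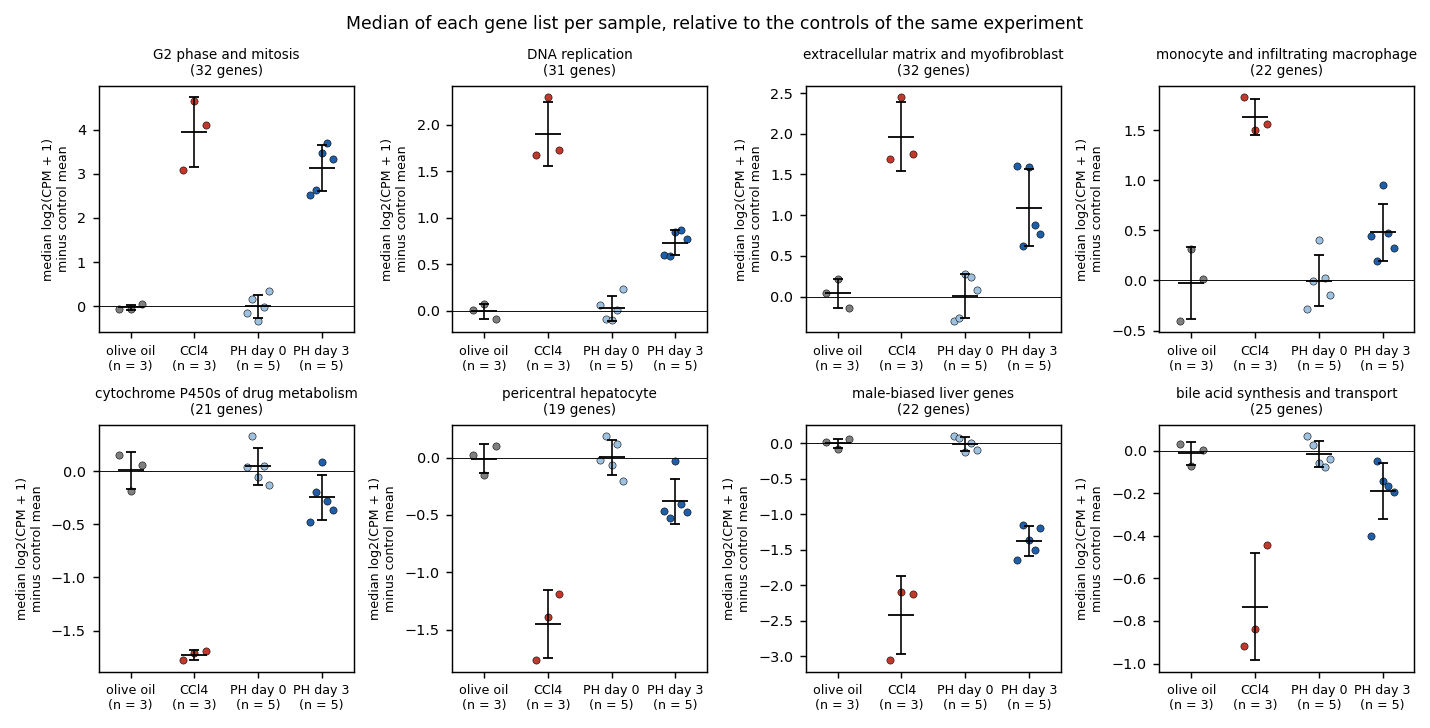
Median over the members of 8 gene lists of log2(CPM + 1) in each sample, minus the mean of the controls of the same experiment, with 1 dot per sample and bars for the group mean and SD (n = 3 per injection group, n = 5 per PH group). The mitosis and male-biased medians of both treated groups lie apart from their controls, and list medians in the text are log2 fold changes from edgeR on another scale.

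The test of the difference (CCl4 minus PH) asks where the changes after CCl4 and PH were unequal. In it, 7 of 19 pericentral and 10 of 21 P450 genes were lower, and 10 of 31 DNA replication genes higher. Of 11868 genes, 174 had a higher and 459 a lower response to CCl4 than to PH (edgeR, adjusted p under 0.05). The contrast was -3.20 ± 0.24 (adjusted p = 1.7e-08) for Glul, -2.59 ± 0.28 (adjusted p = 4.2e-06) for Cyp2e1 and -0.95 ± 0.16 (adjusted p = 0.00077) for Lpcat3, the 3 panel genes that passed. Gpnmb (6.55 ± 1.20, adjusted p = 0.0016), Tubb2b (3.70 ± 0.50, adjusted p = 0.00044), Egr1 (3.53 ± 0.80, adjusted p = 0.024), the replication polymerase Pole (3.45 ± 0.56, adjusted p = 0.00072) and Ccna2 (3.35 ± 0.79, adjusted p = 0.017) had the highest contrasts named by rule, and Cyp2c38 (-8.20 ± 0.84, adjusted p = 1.5e-05), Slc1a2 (-7.43 ± 0.54, adjusted p = 3.4e-06), Gm13775 (-6.92 ± 1.86, adjusted p = 0.0478), Cyp2a5 (-6.57 ± 0.71, adjusted p = 0.00032) and Cyp2a21-ps (-6.56 ± 0.54, adjusted p = 1.7e-06) the lowest. Gpnmb had 4 to 6 counts in each group but CCl4. Gm13775 had no counts after CCl4, at least 58.3-fold lower than olive oil. Calls ended for Egr1 without CCl4 replicate 2 or olive oil replicate 2 or 3 (adjusted p = 0.057 to 0.083, 0.00032 to 0.13 over alternatives) and for Ccna2 without olive oil replicate 2 or 3 (adjusted p = 0.052 to 0.058, 0.00013 to 0.36 over alternatives). That of Gm13775 ended without any 1 sample but PH day 0 replicate 12 or day 3 replicate 15 (adjusted p = 0.051 to 0.13, 0.0019 to 0.21 over alternatives). Library size scaling put 75.9% and upper-quartile scaling 37.6% of called genes on the higher side against 27.5% here, and the first moved the median contrast of all genes by 0.28.

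Of the lists, 23 were called for the difference and 5 of them also passed with an estimated correlation. In the pericentral list 7 of 19 were lower (11 adjusted over the list alone). The median was -1.33, camera adjusted p = 3.6e-23 (1.5e-28 to 0.0024 over alternatives), adjusted p = 0.00037 with an estimated correlation. In the drug-metabolising P450 list 10 of 21 were lower (14 adjusted over the list alone). The median was -1.26, camera adjusted p = 2.0e-21 (2.9e-31 to 0.0025 over alternatives), adjusted p = 0.00037 with an estimated correlation. Of male-biased genes, 7 of 22 were lower (9 adjusted over the list alone). The median was -0.87, camera adjusted p = 7.3e-11 (over alternatives 5.1e-16 to adjusted p = 0.04 with an estimated correlation). Of DNA replication genes, 10 of 31 were higher (19 adjusted over the list alone). The median was 1.27, camera adjusted p = 8.0e-16 (2.1e-17 to 0.014 over alternatives), adjusted p = 0.0056 with an estimated correlation. Of bile acid genes, 9 of 25 were lower (1 and 9 adjusted over the list alone). The median was -0.56, camera adjusted p = 4.7e-06 (2.8e-08 to 0.0461 over alternatives), adjusted p = 0.04 with an estimated correlation, and a median of -0.33 without olive oil replicate 1 and -0.34 without PH day 3 replicate 13. Of mitosis genes, 2 of 32 were higher (2 adjusted over the list alone). The median was 1.47, camera adjusted p = 9.3e-05 (over alternatives 1.9e-08 to adjusted p = 0.38 with an estimated correlation), and the 2 were Ccna2 and Top2a. Macrophage genes Ccr2, Trem2 and Gpnmb were higher, 3 of 22 (5 adjusted over the list alone). The median was 1.20, camera adjusted p = 6.3e-06 (6.5e-09 to 0.15 over alternatives), adjusted p = 0.14 with an estimated correlation. Matrix genes Col4a1 and Mmp14 were higher and Col5a3 lower, so 2 of 32 were higher and 1 lower (2 and 1 adjusted over the list alone). The median was 0.70, camera adjusted p = 0.0036 (0.00023 to 0.41 over alternatives), adjusted p = 0.39 with an estimated correlation.

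Other lists called for the difference with the preset correlation lost that call with the estimated one. Of ribosome biogenesis genes Nop58 was higher, 1 of 18 (3 adjusted over the list alone). The median was 0.47, camera adjusted p = 0.00085 (over alternatives 3.4e-05 to adjusted p = 0.16 with an estimated correlation). Of interferon-stimulated genes, Irf7, Ifi44 and Bst2 were higher, 3 of 18 (7 adjusted over the list alone). The median was 0.85, camera adjusted p = 2.5e-05 (1.5e-07 to 0.15 over alternatives), adjusted p = 0.11 with an estimated correlation. Of liver endothelial genes, Stab1 and Fcgr2b were higher, 2 of 24 (3 adjusted over the list alone). The median was 0.35, camera adjusted p = 0.0036 (over alternatives 0.00082 to adjusted p = 0.21 with an estimated correlation). G1 regulators E2f8 and Rbl1 were higher, 2 of 18 (4 adjusted over the list alone). The median was 0.33, camera adjusted p = 0.0098 (0.0055 to 0.15 over alternatives), adjusted p = 0.14 with an estimated correlation, and a median of 0.21 without olive oil replicate 1 and 0.52 without olive oil replicate 2. Immediate-early genes Egr1 and Ier2 were higher, 2 of 17 (2 adjusted over the list alone). The median was 0.70, camera adjusted p = 0.018 (0.0011 to 0.55 over alternatives), adjusted p = 0.38 with an estimated correlation. That call ended without CCl4 replicate 1 or PH day 0 replicate 15 (adjusted p = 0.0508 to 0.21), and the median was 0.23 without CCl4 replicate 1, 0.45 without PH day 0 replicate 13 and 1.05 without PH day 3 replicate 12.

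Of fatty acid oxidation and ketogenesis, 6 of 29 were lower (12 adjusted over the list alone) in the difference, with median -0.50, camera adjusted p = 3.1e-08 (over alternatives 5.6e-14 to adjusted p = 0.18 with an estimated correlation). In the circadian clock list, with Arntl higher and Tef among the lower members, 1 of 18 was higher and 5 lower (1 and 5 adjusted over the list alone). The median was -0.90, camera adjusted p = 0.0036 (0.00069 to 0.15 over alternatives), adjusted p = 0.11 with an estimated correlation. Of mitochondrial transcripts, mt-Nd2 and mt-Co1 were lower, 2 of 8 (4 adjusted over the list alone). The median was -0.66, camera adjusted p = 0.001 (over alternatives 2.2e-05 to adjusted p = 0.24 with an estimated correlation). Of fatty acid synthesis genes Mlxipl was lower, 1 of 15 (2 adjusted over the list alone). The median was -0.96, camera adjusted p = 7.8e-05 (4.6e-07 to 0.48 over alternatives), adjusted p = 0.28 with an estimated correlation, and a median of -0.62 without CCl4 replicate 1. Periportal genes Ass1, Gls2, Cyp2f2 and Uroc1 were lower and Cdh1 higher, so 1 of 22 was higher and 4 lower (1 and 8 adjusted over the list alone). The median was -0.55, camera adjusted p = 0.00046 (over alternatives 7.4e-10 to adjusted p = 0.11 with an estimated correlation), and -0.88 without CCl4 replicate 1. Of the female-biased genes Cyp2a4 was lower, 1 of 9 (5 adjusted over the list alone). The median was -2.16, camera adjusted p = 3.9e-05 (over alternatives 2.8e-09 to adjusted p = 0.061 with an estimated correlation), and -1.04 without olive oil replicate 1. For triglyceride synthesis and lipid droplets, Dgat2, Fitm1, Lipe and Mgll were lower, 4 of 27 (4 adjusted over the list alone). The median was -0.22, 0.08 with library size scaling, camera adjusted p = 0.036 (over alternatives 0.0001 to adjusted p = 0.38 with an estimated correlation). That call ended without CCl4 replicate 2 or 3, or olive oil replicate 1, or PH day 0 replicate 15, or PH day 3 replicate 16 (adjusted p = 0.057 to 0.23), and its median was -0.34 without CCl4 replicate 1, -0.09 without CCl4 replicate 2, -0.07 without CCl4 replicate 3, -0.13 without olive oil replicate 1 and -0.12 without PH day 3 replicate 13.

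Of lipoprotein and uptake genes, 6 of 31 were lower (2 and 9 adjusted over the list alone) in the difference, with median -0.27, 0.01 with library size scaling, camera adjusted p = 0.0079 (over alternatives 0.00028 to adjusted p = 0.15 with an estimated correlation), a call that ended without CCl4 replicate 3 (adjusted p = 0.059). Of hepatocyte secreted proteins and transcription factors Hpd and Fah were lower, 2 of 28 (1 and 5 adjusted over the list alone). The median was -0.28, camera adjusted p = 0.0079 (over alternatives 9.4e-07 to adjusted p = 0.38 with an estimated correlation), a call that ended without CCl4 replicate 3 (adjusted p = 0.063), with a median of -0.16 there. Of red blood cell transcripts Alas2 was lower, 1 of 6 (1 adjusted over the list alone). The median was -0.65, camera adjusted p = 0.011 (0.0032 to 0.74 over alternatives), adjusted p = 0.38 with an estimated correlation. That call ended without CCl4 replicate 1 or PH day 3 replicate 14 (adjusted p = 0.0505 to 0.057), with a median of -0.23 without PH day 3 replicate 14. The remaining 16 lists tested were not called for the difference. Without CCl4 replicate 1, calls were gained by acute phase (-1.06, adjusted p = 0.0027, 0.0027 to 0.99 over alternatives), NRF2 (0.78, adjusted p = 1.3e-05, 1.3e-05 to 0.84 over alternatives), fasting (-1.49, adjusted p = 5.1e-10, 5.1e-10 to 0.78 over alternatives) and stellate cell genes (0.55, adjusted p = 0.029, 0.029 to 0.92 over alternatives). Elongation and desaturation genes passed without CCl4 replicate 2 (-0.23, adjusted p = 0.017), olive oil replicate 3 (-0.47, adjusted p = 0.016) or PH day 3 replicate 14 (-0.26, adjusted p = 0.039), with 0.016 to 0.53 over alternatives. Cholesterol (0.25, adjusted p = 0.037, 0.037 to 0.996 over alternatives) and Kupffer cell genes (-0.76, adjusted p = 0.018, 0.018 to 0.89 over alternatives) passed without olive oil replicate 1, and oncofetal genes without CCl4 replicate 2 (0.32, adjusted p = 0.0475) or PH day 0 replicate 14 (0.35, adjusted p = 0.0492), with 0.0475 to 0.48 over alternatives. Fry ended the calls of mitosis, matrix, fatty acid synthesis, triglyceride, hepatocyte, immediate-early and red blood cell lists, DESeq2 that of triglyceride genes, limma-voom those of immediate-early genes, Ccna2, Egr1 and Gm13775, library size scaling those of immediate-early genes and Gm13775, and no low-count filter that of Gm13775.

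The shared response asks which genes changed in both kinds of regrowth. Of 10468 genes tested in both comparisons, 983 changed the same way in both, 477 of them downward (178 of 1196 with library size scaling), where independent lists would share 103 risen and 104 fallen genes. Only 2 genes rose after CCl4 and fell after PH (Ier2 and Id2), against 85.6 for independent lists, and 15 fell after CCl4 and rose after PH, against 125. Across genes, which are not independent replicates, the log2 fold changes correlated with Pearson r = 0.739 and Spearman rho = 0.575, against absolute values of up to 0.649 and 0.517 with the PH or all samples regrouped, and no control sample is shared between the comparisons. The risen genes with the largest smaller change were Hmmr, Cenpe, Iqgap3, Ube2c (5.34 after CCl4 and 4.89 after PH) and Prc1 (6.51 and 4.88), all genes of mitosis or cytokinesis. The fallen ones were Hsd3b4 (-4.32 and -3.97), Mup-ps4, Hsd3b5 (-4.59 and -3.34), Gm31583 (-3.12 and -3.15) and Mup17 (-3.87 and -2.30). The Hsd3b5 call after CCl4 ended without CCl4 replicate 2 or 3 or olive oil replicate 1, 2 or 3 (adjusted p = 0.075 to 0.14, 4.0e-09 to 0.14 over alternatives).

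**Figure D3:**
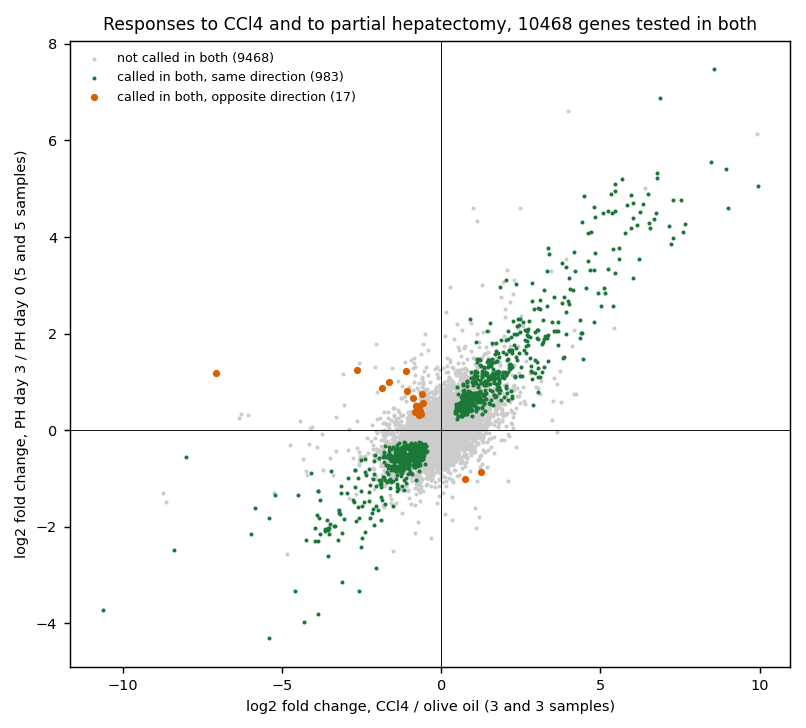
Log2 fold change after CCl4 (horizontal, 3 and 3 samples) against that after PH (vertical, 5 and 5 samples) for the 10468 genes tested in both, 1 point per gene. Genes called in both lie almost wholly in the same direction (983), with 17 opposite, and fitted values of genes without counts in a group are included.

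**Figure D4:**
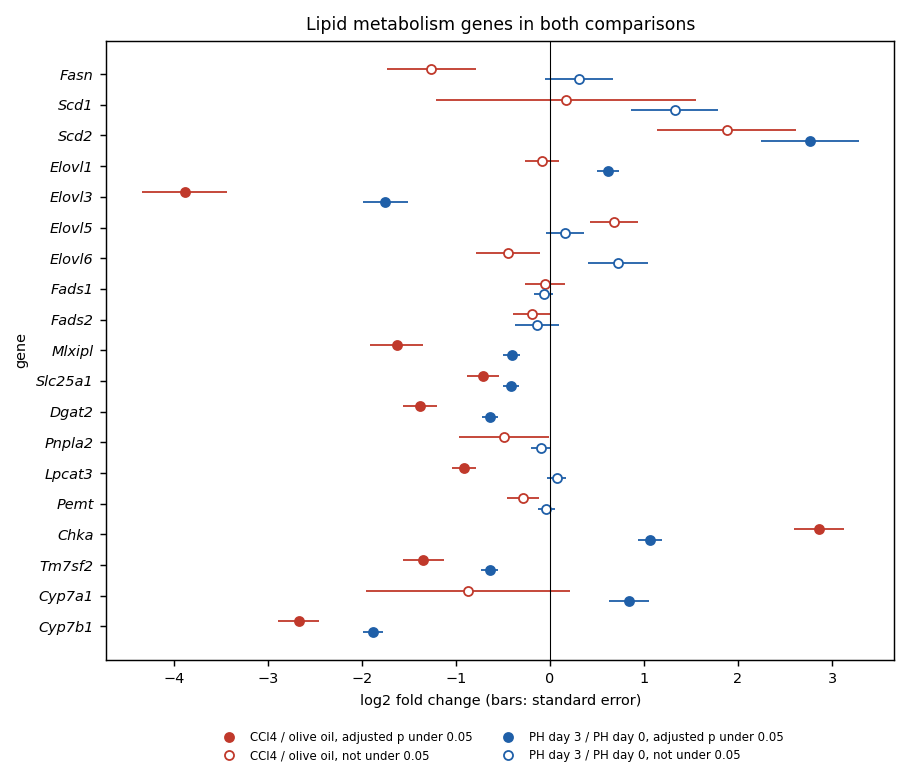
Log2 fold changes of 19 lipid metabolism genes after CCl4 and after PH, with bars for the standard error and filled points for an adjusted p under 0.05 (n = 3 per group for CCl4, n = 5 for PH). Scd1 had a wide standard error after CCl4 (1.38), and Elovl3, Dgat2 and Cyp7b1 fell in both.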

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

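The tests of clock genes and of male-biased genes were chosen only after the result was seen, and those of CCl4 replicate 1 and of other splits of the samples before it. Of 192 groups of 5 samples, 13 held a sample far from the other 4, where chance gives 9.6. The total of PH day 0 replicate 12 was 8647503 counts, the others 3271398 to 4453616. For single genes, the samples that stood apart were PH day 0 replicate 15 with Mki67 at 5.294 CPM (others 0.248 to 1.37), Cdkn3 at 0.6905 CPM (3 counts, the floor, others 0 to 0.131), Ube2c at 1.381 CPM (others 0.248 to 0.524) and Prc1 at 1.841 CPM (others 0.393 to 0.799), PH day 0 replicate 13 with Pnpla2 at 78.27 CPM (others 60.4 to 65.1) and Cyp27a1 at 473.8 CPM (others 554 to 570.0) and PH day 0 replicate 14 with Ccna2 at 3.727 CPM (others 0.991 to 1.71). Others were PH day 0 replicate 12 with Elovl3 at 654.4 CPM (others 299 to 367), PH day 3 replicate 14 with Glul at 622.6 CPM (others 367 to 438) and Cyp2c38 at 37.6 CPM (others 11.4 to 18.6), PH day 3 replicate 16 with Fads1 at 546.1 CPM (others 364 to 414) and PH day 3 replicate 15 with Tpi1 at 378.6 CPM (others 364 to 367).

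Of 52 named genes tested for a difference between the responses to CCl4 and to PH, 22 differed, 13 of them named because they passed this test, with log2 contrasts (CCl4 minus PH) of Alas2 -1.58, Ccna2 3.35, Cdkn1a 2.91, Chka 1.83, Cyp2a21-ps -6.56, Cyp2a5 -6.57, Cyp2c38 -8.20, Cyp2e1 -2.59, Cyp7b1 -0.75, Dgat2 -0.72, Egr1 3.53, Elovl3 -2.10, Glul -3.20, Gm13775 -6.92, Gpnmb 6.55, Lpcat3 -0.95, Mlxipl -1.19, Mup17 -1.54, Pole 3.45, Rrm1 1.09, Slc1a2 -7.43 and Tubb2b 3.70. The lists that differed also with an estimated correlation were DNA replication 1.27, bile acid synthesis and transport -0.56, cytochrome P450s of drug metabolism -1.26, pericentral hepatocyte -1.33 and male-biased liver genes -0.87.

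CCl4 replicate 1 correlated with replicates 2 and 3 at 0.924 and 0.92 in log2 CPM, while these correlated at 0.972. Without the 133 highest genes its mean correlation was 0.9148 (olive oil pairs at least 0.955). All genes weigh alike here, so this cannot test a few abundant genes as the source. Over 3513 genes called without it, its difference from olive oil was 0.7778 of that of replicates 2 and 3 (median), with the same sign in 91.2%, which argues against an olive oil sample under a CCl4 label. No biological explanation was tested.

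Clock genes differed between CCl4 and olive oil, with the median of 5 genes of 1 arm at 1.26 and of 7 genes of the other arm at -1.84, 3.103 apart (bootstrap over genes, not samples, 1.73 to 6.53). A shift that moves all genes alike leaves this distance as it is, which argues against library scaling. Untreated PH day 0 samples, from another experiment, had Tef at 41.9 to 100.1 CPM and Dbp at 5.63 to 51.1 CPM, against 71.3 to 75.8 and 4.02 to 20.4 CPM in CCl4 and 244 to 290.3 and 118 to 157 CPM in olive oil, but Nr1d1 at 127 to 149.9 CPM, against 11.4 to 55.4 and 83.7 to 121 CPM. A difference in the time of culling cannot be told apart from the treatment, since the labels give no such time.

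Male-biased genes fell beyond the hepatocyte list by -2.311 after CCl4 (bootstrap over genes -2.72 to -1.5) and by -1.356 after PH (-1.78 to -0.763), which argues against a lower share of hepatocytes as the whole source. These intervals cover the spread between list members, taken as independent, and not the spread between samples. The 7 members without a near-identical copy had medians of -2.909 after CCl4 (5 fell) and -1.425 after PH (6 fell), which argues against reads shared between paralogs. No biological explanation was tested.

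Among 10 splits of the 6 injection samples, 1 (the real one) gave 2599 genes and the highest other gave 0 with edgeR, with 69 to 464 genes at an unadjusted p under 0.05 against 4092, and the splits are too few for a share under 0.05. For PH, 1 of 100 drawn splits (of 126) gave 1871 genes, the highest other 5, so chance can be excluded. For the shared response, 1 of 100 gave 983 genes, the highest other 0 with edgeR (1738 genes at an unadjusted p under 0.05 in both, the highest other 747), and since regrouped PH samples gave at most 5 calls, this adds nothing on the sharing itself. For the difference, 14 of 100 gave as many as 633 genes, the highest 3048. The other 13 kept the CCl4 and olive oil groups, a structure of the samples that leaves the CCl4 change in the contrast, and the 84 draws that regrouped both experiments gave at most 1, so these draws do not decide whether chance can be excluded.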

How the results depend on the processing

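The alternative joining an estimated correlation with leaving out CCl4 replicate 1 was chosen only after the result was seen. Of the genes named by rule and called, 59 of 74 for CCl4, 61 of 74 for PH and 10 of 13 for the difference kept their call in every alternative, as did 0 of 21, 4 of 10 and 5 of 23 lists (camera), and no called test changed direction. Medians of called lists changed sign with library size scaling for hepatocyte genes after CCl4 (0.08) and triglyceride (0.08) and lipoprotein genes (0.01) in the difference, without CCl4 replicate 1 for immediate-early genes after CCl4 (0.00), and with the identical-label block for red blood cell genes in the difference (0.06). Counts within 1.5 times under all other settings are not listed, and the cause was not tested except where fewer samples or a stricter threshold are the alternative itself. For CCl4, 2599 genes became 1461 with an absolute log2 fold change of at least 1, 1258 with an adjusted p under 0.01, and 1492 to 3513 with 1 sample left out (1623 without CCl4 replicate 2, 1629 without olive oil replicate 1, 1492 without olive oil replicate 3). For PH, 1871 became 581 and 1090 under the same thresholds. The difference went from 633 to 384 to 931 with 1 sample left out (419 without CCl4 replicate 2, 384 without olive oil replicate 3, 931 without CCl4 replicate 1). The shared response went from 983 to 476 with an adjusted p under 0.01 and 356 with the fold threshold. Lists called by camera went from 21 to 0 for CCl4 with an estimated correlation (11 at an unadjusted p under 0.05, 19 by fry), and to 0 also without CCl4 replicate 1 (8 unadjusted). For PH they went from 10 to 16 without a low-count filter and 4 with an estimated correlation, and for the difference from 23 to 5, or 10 without CCl4 replicate 1. With the replicate number as a block the counts were 1864 for PH, 469 for the difference and 987 for the shared response. With only the pairs of identical label as a block, numbers 13 and 14 left out, they were 1500 for PH and 142 for the difference. The block ended the calls of Col1a1, Cyp7a1 and mt-Nd5 after PH and of Egr1 and Gm13775 in the difference, and the identical-label block 8 after PH, including Ccnd1, Cyp7a1, Mlxipl, Elovl3, Hamp, Tpi1 and mt-Nd5, and those of Egr1, Ccna2 and Gm13775 in the difference. With either block Acta2 and fasting genes passed after PH, as did cholesterol genes with the first and acute phase, oncofetal, stellate cell, macrophage and red blood cell genes with the second. The second ended the calls of G1 regulators after PH and of hepatocyte and red blood cell genes in the difference, where elongation and desaturation genes passed. Same-number day 0 and day 3 deviations correlated at 0.049, 0.0757 and 0.112 for identical labels (12, 15, 16). Numbers 13 and 14 had -0.015 and -0.048. Only 16 passed 0.1, and 15 and 16 matched their own number best. Main fits were unpaired. At these depths a gene near the floor of 0.369 to 1.03 CPM is not measurable.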

Other observations

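Gene families were looked at only after the data were seen, 192 after CCl4, 176 after PH and 201 in the difference, and none but Cyp in the difference (camera adjusted p = 0.00238 with an estimated correlation) held with an estimated correlation among those described here. All 21 tested major urinary protein (Mup) genes fell after CCl4 (median -3.50, camera adjusted p = 3.46e-46, adjusted p = 0.801 with an estimated correlation) and after PH (median -2.02, camera adjusted p = 1.83e-47, adjusted p = 0.265 with an estimated correlation), also with library size scaling, and these near-identical genes have uncertain single values. Nucleoporin (Nup) genes rose after CCl4 in 8 of 18 (median 0.65, and 14 of 18 with median 1.11 with library size scaling, camera adjusted p = 0.000457, adjusted p = 0.801 with an estimated correlation) and 2 of 18 after PH, with 5 of 18 higher in the difference (median 0.58, camera adjusted p = 5.52e-05, adjusted p = 0.0846 with an estimated correlation).

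The acute phase transcript Saa1 varied within groups. It was 140, 4485 and 1841 CPM in olive oil replicates 1 to 3, 1900, 247 and 69.3 CPM in CCl4 replicates 1 to 3, 81.7 to 3285 CPM at PH day 0 and 318 to 6358 CPM at PH day 3. PH day 0 replicate 12 had Dbp at 5.63, Nfil3 at 56.9 and Arntl at 26.9 CPM, against 18.1 to 51.1, 12 to 20.1 and 9.91 to 12.3 CPM in the other day 0 samples.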
